A study of Homo sapiens with 6 samples.

How the data were processed

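RNA was measured in U2OS cells, a human osteosarcoma cell line, that carried an inducible Myc expression vector. Per the labels' protocols, cells were induced or mock-treated for 36 h, polyA RNA was taken, and libraries were made with the TruSeq RNA kit. There were 6 libraries in 4 groups: control (n = 2), Myc (n = 2), and 1 library each of cells given Torin-1, an inhibitor of the mTOR kinase, without and with Myc induction. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

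The authors deposited FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) for 9578 genes, 1 value per gene and library, rounded to 1 decimal. No value lay below 1, a floor applied by the authors per the table's own name, and 20 genes sat at that floor in every library. The submitters' processing notes name Bowtie without a version or a role; the genome build, the annotation and the counting step are not given in the sources used here. Read counts were not used here, so the depth of each library is unknown, no counting error could be given, and values near the floor carry the least information. The floor and the added pseudocount both understate the change of low genes. Reads from the Myc vector may be counted with the endogenous MYC gene, since nothing states how they were handled. Spreadsheet conversion had turned 12 symbols into dates, and these were restored from their Ensembl identifiers.

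All tests used log2(FPKM + 1), so that a log2 change is on that scale. Because FPKM is scaled to the mapped fragments of each library, a rise or fall is relative to the other genes. A change in the total RNA of a cell would not show. Genes were tested where at least 2 of the 6 libraries had a value of at least 1 and above the floor, which left 9537. Moderated tests came from limma 3.58.1 in R 4.3.3 (eBayes with a spread that follows mean expression, 2-sided, Benjamini-Hochberg adjusted p with a threshold of 0.05). Myc induction was tested on the 4 libraries without Torin-1. Torin-1 was tested over all 6 libraries in a model where the Myc and Torin-1 effects add, and there a response that differs between the Myc states counts as spread. The difference of the Myc response between cells with and without Torin-1 was tested as an interaction over the 4 group means. The Torin-1 tests assume that the lone libraries vary like the replicated ones. The Myc response within the Torin-1 pair has 1 library per group and is given as values.

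A further fit was chosen after the data were seen. The 2 replicate 1 libraries stood apart from the other 4, and this split was added as a term, called the library set, to each of the 3 fits. For Myc induction and the interaction it gives the same calls as the replicate block, an alternative fixed with the design. In the Myc and interaction fits with the term the residual spread of a gene comes only from how far the Myc minus control differences of the replicate pairs disagree. Variation shared by both libraries of a pair does not enter it, nor does any variation of the lone Torin-1 libraries. In the Torin-1 fit with the term, a Torin-1 response that differs between the Myc states also counts as spread. For Torin-1 the term assumes that the Torin-1 libraries belong with replicate 2, which rests on the values and not on the labels. The values are mixed on this. The principal component that parted the libraries placed the Torin-1 libraries with replicate 2. Their MT-ND4L values and the FPKM share of their most abundant genes lay between the sets. The deposited table's name speaks of more than 1 round of the experiment without saying which library belongs to which. The steps were tested on simulated data with 200 changed genes among the 9537. The simulated libraries held the library set effect and the spread of the fit with the term. The Torin-1 libraries were placed with replicate 2 and given no deviation of their own beyond noise. The simulation therefore cannot test whether the term or that placement is right for the real libraries. For Myc induction limma without the term recovered 0 of 67 genes changed 1.5-fold, 0 of 67 changed 2-fold and 0 of 66 changed 4-fold, and with the term 55, 65 and 62, with 1 false call among 9337 unchanged genes. For Torin-1 the numbers were 0, 17 and 48 without the term and 66, 66 and 65 with it, with 3 false calls. For the interaction they were 0, 0 and 0 without and 19, 60 and 63 with the term, with 1 false call. List tests were simulated for Myc induction alone, where the list that was moved was called and 0 of 29 others, both with and without the term. Genes varied independently there, so this does not test the preset correlation of the list tests.

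Before the data were examined, 32 gene lists were fixed from textbook knowledge of Myc, mTOR signalling, U2OS cells and RNA quality, and the 30 with at least 5 tested members were tested. The test was camera (limma) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. With an estimated correlation camera bases p on the residual degrees of freedom of the fit, which are few here. A call lost in that setting was therefore close to fixed in advance and by itself says little about the list. The size of the estimated correlation is a separate matter. Where it lies far above 0.01, the p with the preset correlation may be too small. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone. A list's median in the Torin-1 pair was placed among 10000 random lists of its size matched on mean expression in 20 bins. The rule for naming genes was also fixed then: MYC always; per comparison up to 8 genes with the largest change in each direction among those past the threshold with a mean of at least 5 FPKM in the higher group and no overlap of the groups' libraries (4 per direction for the interaction, or the 5 with the smallest p where none passed); and per list up to 4 members past the threshold with the largest change, otherwise the 2 with the smallest p. The rule was applied to the planned fits and repeated on the fits with the library set term. Results for a few genes and 1 list are not reported here.

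Transcript GC content and length came from GENCODE release 29 (GRCh38), matched by transcript identifier for 9016 of the 9537 tested genes (94.5%), and gene positions are those of that annotation, matched for 9501 genes. In an added check each library's trend over GC content and length was removed with natural splines (5 degrees of freedom each). Alternatives fixed with the design were pseudocounts of 0.1 and 5, no filter, a stricter filter (mean of at least 5 FPKM), quantile normalization, median-ratio scaling, a replicate block, a prior spread without a trend, leaving out each replicate, and each Myc state alone for Torin-1. Each was repeated with the library set term where that fit could be made. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.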

Results

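The series asks how inducible Myc changes gene expression in U2OS cells, and what the response looks like when mTOR is inhibited with Torin-1. The 6 libraries had FPKM totals between 432629 and 474981 over the 9578 genes, medians between 14.8 and 15.8 FPKM, and between 47 and 210 genes at the floor of 1. Read depth is unknown. Across the tested genes the leading principal component (44.6% of the variance) parted libraries with from those without Myc induction. The next (36.2%) parted both replicate 1 libraries from the other 4, and the component after it (15.3%) lay mostly between control replicate 2 and the Torin-1 library. The 10 most abundant genes took 13.2% of the FPKM total in each replicate 1 library, 9.09% and 8.83% in control and Myc replicate 2, and 10.6% and 10.3% in the Torin-1 and Myc plus Torin-1 libraries. MT-ND4L, encoded in the mitochondrial genome, stood at 7498 and 7778 FPKM in the control and Myc libraries of replicate 1, and at 1639 and 2033 FPKM in those of replicate 2. The Torin-1 and Myc plus Torin-1 libraries had 3604 and 3502 FPKM. This split of the libraries was therefore carried through every comparison.

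MYC itself was the largest change after induction. MYC (ENSG00000136997; chromosome 8, 127735434 to 127741434, + strand) went from 82.3 ± 5.94 FPKM in control to 5076 ± 823 FPKM in Myc libraries (SD, n = 2 each), a log2 change of 5.92 (SE 0.20, limma adjusted p = 0.0450). Without induction the Torin-1 library had 194.7 FPKM, and with induction 5050.7 FPKM. MYC was the 1 gene of 9537 that passed limma as planned, and 1454 had an unadjusted p under 0.05. With the library set as a term, chosen after the data were seen, 5735 genes passed limma: 2979 rose and 2756 fell, 152 and 289 of them by over 2-fold. Their p rests on how closely the replicate pairs agreed, with the difference between the library sets taken out. In the separate replicate pairs 115 genes were over 2-fold higher in both and 208 over 2-fold lower in both, and the pairs' log2 differences correlated across genes with r = 0.926 (genes are not independent replicates). Changes of single genes given here passed limma with the term, and apart from MYC none of these genes passed in the planned fit, which has no term for the split. MYC lost its call when any 1 of the 4 libraries was left out (0 genes passed in each case), and also with no filter or without the trend in the prior spread.

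Among the genes that rose most were several of the early response to growth signals. EGR1, an immediate early transcription factor, rose from 9.80 ± 3.11 to 112 ± 26.6 FPKM (log2 change 3.40, SE 0.07; limma adjusted p = 1.46e-08). FOS rose from 2.55 ± 0.919 to 13.9 ± 3.25 FPKM and ARC from 25.6 ± 5.16 to 114 ± 11.6 FPKM. RGS16, a regulator of G-protein signalling, rose from 7.65 ± 1.06 to 49.5 ± 9.40 FPKM. CAMKV (log2 change 3.34), the inducible heat shock gene HSPA6 (2.38) and the phosphodiesterase gene PDE1B (2.07) came from values below 2 FPKM in control. The largest falls were in OLFML3, at 17.6 ± 3.39 FPKM in control and 2.0 ± 0.141 FPKM after induction, and in TMSB4X, which encodes the actin-sequestering thymosin beta-4, at 184 ± 47.3 and 30.4 ± 4.31 FPKM. LOXL4, a lysyl oxidase that cross-links collagen, fell by 2.34 on the log2 scale, as did PALM3 (-2.31), the cytidine deaminase gene CDA (-2.28), NTM (-1.96) and ODZ2 (-1.96).

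**Figure D1:**
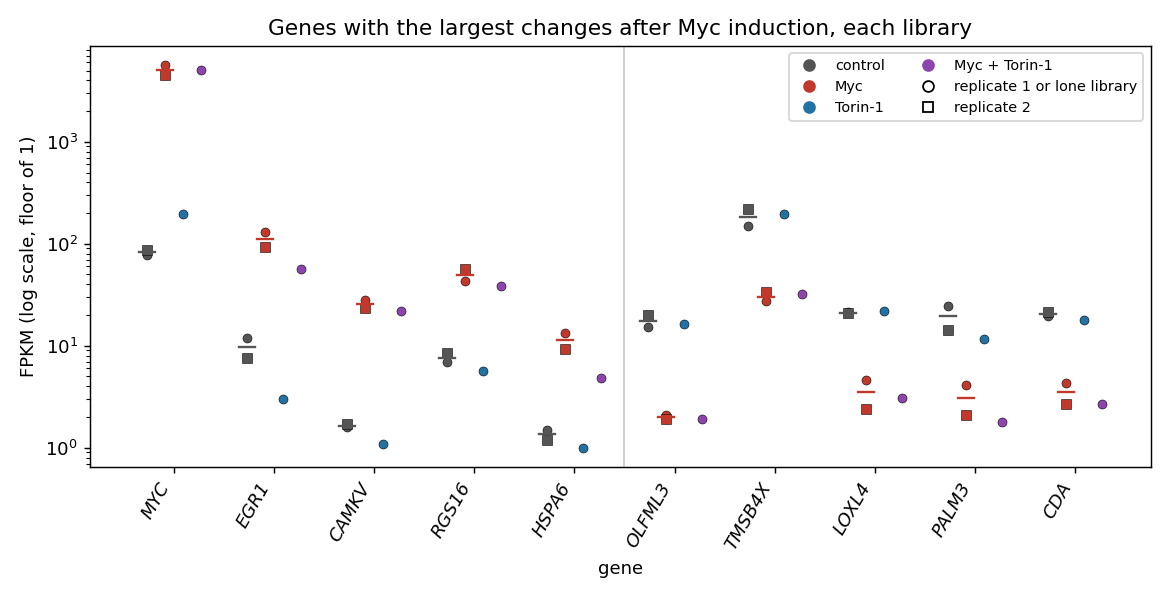
FPKM (log axis, floor of 1) of the 5 genes with the largest rise and the 5 with the largest fall after Myc induction, 1 point per library, with a short line at the mean of the 2 control and of the 2 Myc libraries. MYC stood at 82.3 FPKM in control and 5076 FPKM in Myc libraries on average, TMSB4X at 184 and 30.4, and the libraries with Torin-1 (no replicates) lay near the matching libraries without it for most of these genes.

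Ribosome assembly rose as a group while the ribosomal proteins did not. Of 39 nucleolar ribosome biogenesis genes 35 rose and 0 fell (36 and 0 adjusted over the list alone), with a median log2 change of 0.51. RRP9, a component of the U3 small nucleolar particle, went from 71.2 ± 6.29 to 180 ± 28.0 FPKM, and RRP12 rose by 1.19, LYAR by 1.12 and the RNA polymerase I subunit gene POLR1B by 0.82 on the log2 scale. Camera, in limma, gave this list an adjusted p = 3.19e-10 without the library set term, and adjusted p = 0.627 with an estimated correlation. Of 80 genes for cytosolic ribosomal proteins and elongation factors 41 fell and 1 rose (39 and 1 adjusted over the list alone), with a median of -0.17. RPS27 fell by 0.48, RPL28 by 0.43, the elongation factor gene EEF1A1 by 0.40 and RPS2 by 0.37. This list had camera adjusted p = 0.0152, and adjusted p = 0.835 with an estimated correlation. It lost the call with quantile normalization (median -0.05) and with the GC content and length correction (-0.13), and stood at 0.03 without control replicate 2. Among 35 translation initiation factors 19 rose and 2 fell (19 and 2 adjusted over the list alone), with EIF2B3 up by 0.83, EIF3J by 0.73 and EIF3B by 0.53, while EIF4EBP2, a repressor of cap-dependent initiation, fell by 0.59. Among 41 genes of the mitochondrial ribosome and import 28 rose and 1 fell (29 and 1 adjusted over the list alone), among them MRPS30 (0.90), MRPS2 (0.69), the import channel gene TOMM40 (0.60) and TIMM50 (0.58). Camera adjusted p was 0.0282 and 0.00147 for these 2 lists, and adjusted p = 0.774 with an estimated correlation for both. Of 20 aminoacyl-tRNA synthetase genes 14 rose and 3 fell, by p over all genes and adjusted over the list alone. That list missed the threshold in camera as planned (adjusted p = 0.0610) and passed with the library set term (adjusted p = 0.0165, and adjusted p = 0.513 with an estimated correlation), a call that ended with the GC content and length correction (0.20, camera adjusted p = 0.0605).

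Stress-response, heat shock and clock genes also rose. In the list of ATF4 targets and the integrated stress response 23 of 30 rose and 4 fell (23 and 5 adjusted over the list alone), with a median of 0.46. CTH, an enzyme of cysteine synthesis, rose from 4.0 ± 1.56 to 18.8 ± 7.35 FPKM, the transcription factor ATF3 by 1.5, the glutathione-degrading CHAC1 by 1.32 and DDIT3, which encodes the stress factor CHOP, by 1.17 on the log2 scale. Of 12 core clock genes 9 rose and 0 fell (10 and 0 adjusted over the list alone), with NR1D1 up by 1.72, PER2 by 1.71, PER1 by 1.56 and CRY2 by 1.09. Camera adjusted p was 1.75e-04 for the stress-response list, with adjusted p = 0.698 with an estimated correlation. For the clock list it was 1.04e-04, with adjusted p = 0.627 with an estimated correlation. Among 21 cytosolic chaperones 16 rose and 1 fell, also when adjusted over the list alone. HSPA1B (1.83) and HSPA1A (1.68) rose, though these near-identical copies share reads and their split is uncertain, BAG3 rose by 0.81, and HSPB1 fell by 0.63. Camera adjusted p was 0.00287, and adjusted p = 0.774 with an estimated correlation. Of 15 immediate early genes 10 rose and 3 fell, also when adjusted over the list alone, EGR1, FOS, DUSP5 (1.11) and KLF10 (1.05) among those that rose (camera adjusted p = 0.00192, and adjusted p = 0.745 with an estimated correlation). In the Myc network 11 of 14 rose and 2 fell, also when adjusted over the list alone: the dimer partner gene MAX rose by 0.79 and MXD1 by 1.11, while MXD3 fell by 1.68 and MXD4 by 0.64, the MXD proteins being antagonists of Myc at MAX (camera adjusted p = 0.0482, and adjusted p = 0.698 with an estimated correlation). Of 7 replication-dependent histone genes, a check on polyA selection, 5 rose and 1 fell, also when adjusted over the list alone. HIST1H2BJ rose by 1.15, HIST1H4H by 1.0 and HIST1H2BK by 0.98, and HIST1H1C fell by 0.79. Camera called the histones as planned (adjusted p = 0.0482, and adjusted p = 0.774 with an estimated correlation) but not with the library set term (adjusted p = 0.141). The planned histone call also ended with no filter, with the stricter filter, with quantile normalization (adjusted p = 0.0527, 0.0548 and 0.0524) and with the GC content and length correction (median 0.21 in place of 0.32, adjusted p = 0.321).

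Adhesion, matrix, mitotic, lipid synthesis and interferon genes fell. In the extracellular matrix list 20 of 29 fell and 2 rose, with a median of -0.51, and in the integrin and focal adhesion list 18 of 25 fell and 1 rose, with a median of -0.37; both pairs of counts were the same adjusted over the list alone. LOXL2 fell by 1.70, TGFBI by 1.49, LOXL1 by 1.43 and the membrane protease gene MMP14 by 1.42 on the log2 scale. CAV1, which encodes caveolin-1, went from 47.8 ± 7.0 to 11.8 ± 0.778 FPKM, while TNS3 fell by 1.49, ITGA3 by 1.38 and ITGA7 by 0.87. Of 23 genes that respond to YAP, SRF or TGF-beta 14 fell and 3 rose (14 and 3 adjusted over the list alone), including TPM1 (112 ± 6.43 to 29.2 ± 4.74 FPKM), TGFB1I1 (-1.77), TGFB2 (-1.38) and CNN1 (-1.15). Camera adjusted p was 5.04e-04 for matrix, 0.00117 for integrins and 5.04e-04 for the YAP, SRF and TGF-beta list, and adjusted p = 0.774 with an estimated correlation in all 3. Among 32 mitosis genes 25 fell and 1 rose (26 and 1 adjusted over the list alone), with KIF20A down from 65.3 ± 0.283 to 33.5 ± 3.89 FPKM, CDC25C by 0.88, CDC25B by 0.83 and TOP2A by 0.76 (camera adjusted p = 8.97e-04, and adjusted p = 0.698 with an estimated correlation). Of 31 sterol and fatty acid synthesis genes 22 fell and 3 rose, also when adjusted over the list alone. ACAT2 and FADS2 each fell by 1.36, ACSS2 by 1.32 and FADS1 by 1.02, and camera adjusted p was 0.00192, with adjusted p = 0.774 with an estimated correlation. Among 18 interferon-stimulated genes 12 fell and 0 rose, also when adjusted over the list alone, with the immunoproteasome gene PSMB9 (-1.53), OAS3 (-1.22), STAT2 (-0.89) and IFI6 (-0.67) (camera adjusted p = 0.00147, and adjusted p = 0.627 with an estimated correlation). CLDN4, an epithelial tight junction gene and the 1 measured member of an epithelial marker list, fell from 8.0 ± 0.707 to 1.85 ± 0.0707 FPKM. In all, camera called 16 lists as planned, and between 10 and 14 when 1 library was left out. Without control replicate 1 the calls of matrix (median 0.00), integrins (-0.10), the mitochondrial ribosome (0.01), initiation factors (0.06) and chaperones (0.18) ended, and the medians of these 5 lists without Myc replicate 2 were -0.12, -0.09, 0.04, 0.05 and 0.13 with their calls ended as well. The histones lost their call without either of these libraries, the Myc network without control replicate 1 (0.60), Myc replicate 1 (0.29) or control replicate 2 (0.29), with no filter (0.51) or with the stricter filter (0.51), the ribosomal proteins without Myc replicate 1 (-0.04) or control replicate 2, and lipid synthesis without control replicate 2 (-0.10). A fit without 1 library and without the term leaves Myc unbalanced against the library set. Its medians therefore hold part of the difference between the sets. In the separate replicate pairs the medians were -0.58 and -0.44 for matrix, -0.47 and -0.35 for integrins and 0.27 and 0.27 for the mitochondrial ribosome. They were 0.21 and 0.18 for initiation factors and 0.20 and 0.22 for chaperones.

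The Myc response in the presence of Torin-1 was compared as values, with 1 library per group. The difference between the Myc plus Torin-1 and the Torin-1 library correlated across genes with the mean response without Torin-1 (r = 0.75, Spearman rho = 0.740). With pair 1 alone r was 0.778 and with pair 2 alone 0.697. Of the 2979 genes that rose after induction 2595 (87.1%) were higher in the Torin-1 pair, and of the 2756 that fell 2558 (92.8%) were lower, against 48.9% higher and 50.1% lower over all genes. Their median log2 differences were 0.41 without and 0.47 with Torin-1 for the genes that rose, and -0.46 and -0.45 for those that fell. The median of the nucleolar ribosome biogenesis list was 0.54 and 0.51 in the replicate pairs and 0.62 in the Torin-1 pair, above all 10000 random lists of its size. The mitochondrial ribosome list stood at 0.27, 0.27 and 0.47, and the core clock at 0.61, 0.79 and 0.77. The matrix list stood at -0.58, -0.44 and -0.76, mitosis at -0.36, -0.26 and -0.46, the YAP, SRF and TGF-beta list at -0.49, -0.58 and -0.52, and sterol and fatty acid synthesis at -0.34, -0.31 and -0.45, each below all 10000 random lists in the Torin-1 pair. Cytosolic ribosomal proteins had -0.10 and -0.24 without and 0.02 with Torin-1. Among random lists matched on mean expression that 0.02 was still low, at percentile 0.32. The random lists were not matched on GC content or length, and the difference within the Torin-1 pair followed both. Its Spearman rho across genes was 0.333 with GC content and -0.196 with length. GC content and length together accounted for 16.3% of its variance, against 0.702% and 2.91% in replicate pairs 1 and 2. The percentiles therefore cannot tell a list's Myc response apart from that trend.

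**Figure D2:**
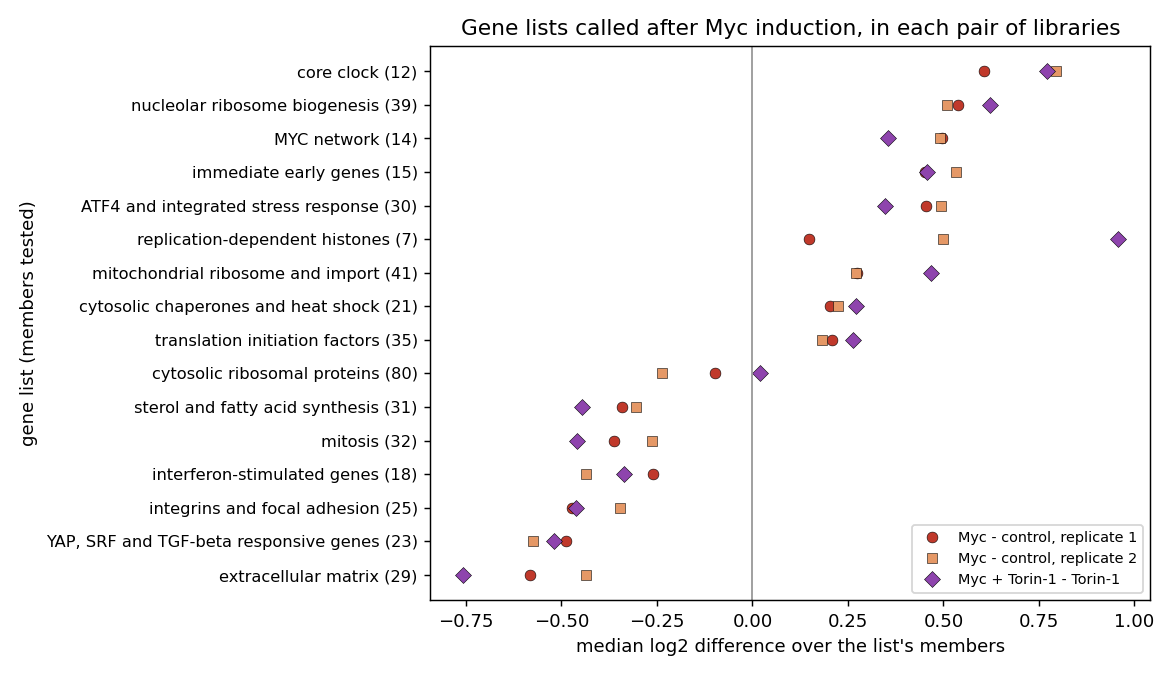
Median log2 difference over the members of each of the 16 gene lists that camera called after Myc induction, as circles and squares for the 2 replicate pairs without Torin-1 and diamonds for the single pair with Torin-1. In 15 of the lists all 3 medians lay on the same side of 0, and the cytosolic ribosomal proteins had -0.10, -0.24 and 0.02. The last was at percentile 0.32 of random lists matched on mean expression but not on GC content or length.

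A small group of genes was higher with Torin-1 in both Myc states. C8orf4 (TCIM), which encodes a small regulatory protein, was at 5.0 and 4.3 FPKM in the control libraries, at 3.1 and 2.6 FPKM in the Myc libraries, and at 40.0 and 36.1 FPKM in the Torin-1 and Myc plus Torin-1 libraries (log2 change 3.07, SE 0.17, limma adjusted p = 0.0169). PIM1, a serine/threonine kinase, was at 9.8 and 12.2 FPKM in control, 5.1 and 5.0 FPKM in Myc, and 69.6 and 35.2 FPKM with Torin-1 (log2 change 2.57, SE 0.15, limma adjusted p = 0.0169). These were the 2 genes that passed limma as planned, with 910 at an unadjusted p under 0.05. With the GC content and length correction C8orf4 missed the threshold (log2 change 2.69, SE 0.35, limma adjusted p = 0.0886). Its SE was larger than the 0.17 before. PIM1 passed (2.73, SE 0.14, limma adjusted p = 0.0213). With the library set as a term 52 genes passed, and all 52 were higher in both Myc states, 34 of them by over 2-fold in each. The additive fit favours such agreement, since a response that differs between the Myc states counts as spread. The largest after C8orf4 (3.16 in this fit) were INHBA, which encodes a subunit of activin (2.52), PIM1 (2.51), the circadian and hypoxia-responsive repressor BHLHE40 (2.19), the repressor BCL6 (2.06), the co-activator CITED2 (2.0), the phosphatase DUSP1 (1.94) and the kinase SGK1 (1.89). Without the term 5 of the 52 had a log2 change below 0, named after their values were seen: PLEC (-0.36), HSPG2 (-0.15), PKD1 (-0.07), FASN (-0.04) and MYH9 (-0.04).

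Targets of FOXO and of PI3K feedback were higher with Torin-1 as a group and had the smallest p of the planned list tests for Torin-1. BCL6, KLF6 (1.79) and PIK3IP1 (1.13), an inhibitor of PI3K, rose with the library set term, and adjusted over the list alone 12 of 20 rose and 1 fell. The median log2 change was 0.44 without and 0.64 with the term, with camera adjusted p = 4.17e-05 and 3.27e-06, and adjusted p = 0.407 and 0.436 with an estimated correlation. The list of CDK inhibitors and Miz1-bound genes (median 0.24), mitosis (0.27) and the histones (0.61) were also called higher as planned, with camera adjusted p = 0.00740, 0.00799 and 0.00740, and adjusted p = 0.589, 0.597 and 0.701 with an estimated correlation. With the term these 3 medians were 0.48, 0.12 and 0.26, with camera adjusted p = 0.00503, 0.00639 and 0.0344, and adjusted p = 0.436, 0.436 and 0.551 with an estimated correlation. In that fit GADD45A rose by 1.16, while CENPA (0.47) and MKI67 (0.82) did not pass. Adjusted over the list alone 5 members of the list of CDK inhibitors and Miz1-bound genes rose and 1 fell. Not all members of that list are CDK inhibitors. Over their lists alone 1 mitosis gene rose and 2 histones rose. Glycolysis (-0.24) and cytosolic ribosomal proteins (-0.06) were called lower, with camera adjusted p = 0.00799 and 0.0476, and adjusted p = 0.597 and 0.865 with an estimated correlation. No member of either passed limma with the term over all genes or adjusted over the list alone, and with quantile normalization both calls ended (-0.19 for glycolysis, 0.04 for ribosomal proteins). The ribosomal protein call also ended with no filter, with the stricter filter, without the trend in the prior spread and with the GC content and length correction (0.03). With the term the ribosomal proteins stood at -0.22, oxidative phosphorylation at -0.26 (NDUFS8 at -0.60), the mitochondrial ribosome at -0.24, the proteasome at -0.21, replication at -0.14 and cytosolic chaperones at -0.14 (0.01, uncalled, with quantile normalization). The ribosomal protein call with the term ended with quantile normalization (-0.05) and with the GC content and length correction (-0.019), the proteasome call ended with quantile normalization (-0.05), and without the term the mitochondrial ribosome (0.012), the proteasome (-0.0076), chaperones (-0.02), oxidative phosphorylation (-0.07) and replication (-0.13) were not called. Camera called all 6 lower (adjusted p between 9.08e-10 and 0.0165, and adjusted p = 0.551 with an estimated correlation), with 2 oxidative phosphorylation genes and 3 chaperone genes lower adjusted over the list alone. Without the Torin-1 library the planned calls of mitosis (0.20), glycolysis (-0.12) and ribosomal proteins (0.05) ended, as did that of the histones without the Myc plus Torin-1 library (0.30) and that of the ribosomal proteins without control replicate 2 (0.05) or Myc replicate 2 (-0.0059).

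With the term camera also called the matrix (median 0.40), the YAP, SRF and TGF-beta list (0.20), integrins (0.08), autophagy and lysosome (0.12), inflammatory genes (0.22) and mitochondrially encoded genes (0.49) higher with Torin-1, with adjusted p = 1.01e-07, 0.00683, 0.00503, 0.0186, 0.0300 and 0.00683, and adjusted p = 0.436 with an estimated correlation for each. THBS1 rose by 1.82 and the basement membrane gene HSPG2 by 1.03 on the log2 scale, with 15 of 29 matrix genes higher adjusted over the list alone. INHBA and ANKRD1 (1.79) rose in the YAP, SRF and TGF-beta list, where 7 rose and 2 fell adjusted over the list alone. Adjusted over the list alone 5 integrin, 1 autophagy and 3 mitochondrially encoded genes rose, and of the inflammatory genes TNFAIP3, a negative regulator of NF-kB, rose by 1.16 on either count. Without the term the matrix and integrin lists stood at -0.17 and -0.22, on the other side of 0, as did mitochondrially encoded genes (-0.07) and the YAP, SRF and TGF-beta list (-0.0039), and neither these nor autophagy (0.07) and inflammatory genes (0.03) were called. Mitochondrially encoded genes, fixed as a check of RNA quality, also lost their call with quantile normalization (0.27). Their median difference from the matching replicate 2 library was 0.49 without and 0.44 with Myc. They thus moved along with the genes and lists called higher. Without the Myc plus Torin-1 library the calls of integrins (0.04), the YAP, SRF and TGF-beta list (0.09), autophagy (0.11), inflammatory genes (0.24), histones (0.012) and mitochondrially encoded genes (0.45) ended, and without Myc replicate 2 those of autophagy (0.13), inflammatory genes (0.20) and histones (0.35). Glycolysis, called lower with the term (-0.15, adjusted p = 0.0244, and adjusted p = 0.627 with an estimated correlation), lost its call without the Torin-1 library (-0.07), with quantile normalization (-0.08) and with the GC content and length correction (-0.07). Among single genes outside the largest changes, DUSP5 rose by 1.76, PPP1R15A by 1.20, FASN by 0.76 and FOSL2 by 0.68. The count of 52 was 0 without control replicate 1, 0 without Myc replicate 1, 14 without control replicate 2, 15 without Myc replicate 2, 516 without the Torin-1 library (290 higher) and 4549 without the Myc plus Torin-1 library (2146 higher), each of the last 2 with all 52 among them. The planned count of 2 was 0 when any 1 library other than control replicate 2 was left out.

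**Figure D3:**
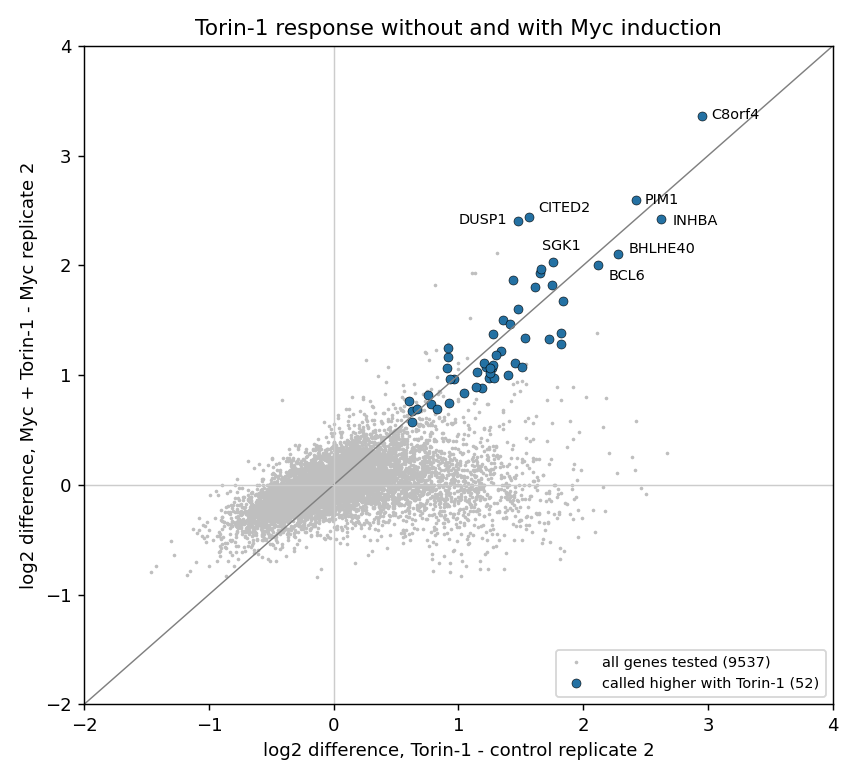
Log2 difference with Torin-1 for each of the 9537 tested genes without Myc induction (x axis, Torin-1 minus control replicate 2) and with it (y axis, Myc plus Torin-1 minus Myc replicate 2), 1 library per group, with the line of equal differences. The 52 genes called higher with Torin-1 (blue) lay above 0 on both axes, which the additive fit that called them favours, with C8orf4 at 2.95 and 3.37.

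The Torin-1 library differed from control replicate 2 far more than the Myc plus Torin-1 library did from Myc replicate 2. The SD over genes of the log2 difference was 0.50 and 0.25, and the correlation between them across genes was r = 0.438. Long and AT-rich transcripts were higher in the Torin-1 library: its difference from control replicate 2 had a Spearman rho across genes of -0.579 with GC content and 0.505 with length. The fifth of genes with the lowest GC content had a median of 0.49 and the fifth with the highest -0.28. For the Myc plus Torin-1 library against Myc replicate 2 these medians were -0.05 and -0.06 (rho -0.033 with GC content). Longer transcripts were higher there too (rho 0.319 with length). The fifth of shortest and the fifth of longest transcripts had medians of -0.32 and 0.27 for the former difference and -0.12 and 0.04 for the latter. GC content and length together accounted for 45.2% of the variance of the former difference and 10.8% of the latter.

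**Figure D4:**
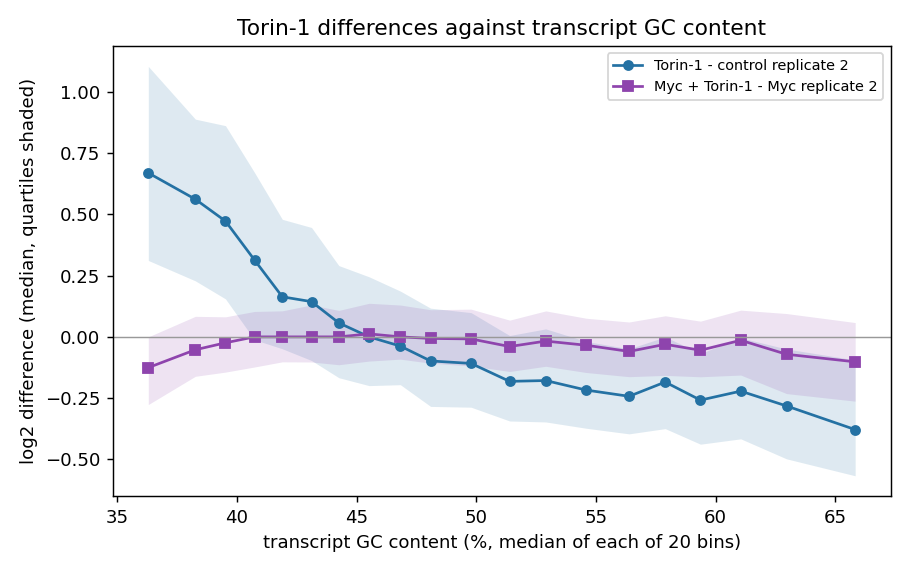
Median log2 difference (lines) and quartiles (shading) of genes in 20 bins of transcript GC content for Torin-1 minus control replicate 2 and Myc plus Torin-1 minus Myc replicate 2, 1 library per group. The median in the bin of lowest GC content was 0.67 for the former and -0.13 for the latter.

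With the library set as a term 1198 genes had a Myc response that limma called different in the presence of Torin-1, 206 higher and 992 lower, while limma as planned called 0 of 9537 genes (216 at an unadjusted p under 0.05). The spread behind these calls came from the control and Myc pairs alone, so no variation of the lone Torin-1 libraries was measured. JMJD1C (-2.41), KIAA1551 (-2.28), the kinetochore gene CENPF (-2.27) and KTN1 (-2.21) had the most negative interactions, and CD274, which encodes PD-L1 (1.09), CSRNP1 (0.91), FOXD1 (0.87) and CTGF (0.87) the most positive. The 5 genes with the smallest p in the planned fit did not pass: CREBRF (-1.92), BIRC3 (-2.05), LARP7 (-1.84), ETAA1 (-1.33) and CUL5 (-1.54), all with limma adjusted p = 1.0. MYC had an interaction of -1.23 (limma adjusted p = 0.00277 with the library set term and 1.0 as planned), with a log2 difference of 4.69 in the Torin-1 pair. Of the 992 lower genes 991 had a higher value in the Torin-1 library than in control replicate 2, and of the 206 higher genes 189 had a lower value there. Selection favoured these counts. The interaction subtracts that difference, whose SD over genes was 0.50, against 0.25 for Myc plus Torin-1 minus Myc replicate 2. The median transcript GC content was 39.0% in the lower, 59.1% in the higher and 48.9% in all tested genes, and the median length 4869, 1629 and 3163 bases. After each library's trend over GC content and length was removed 841 genes passed, 475 of them also among the 1039 called on the same 9016 genes without that correction.

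By list, camera as planned called 6 with a higher Myc response in the presence of Torin-1: cytosolic ribosomal proteins (median interaction 0.20), oxidative phosphorylation (0.24), the mitochondrial ribosome (0.24), the proteasome (0.17), glycolysis (0.22) and histones (0.59). Their adjusted p was 6.97e-04, 6.97e-04, 0.00258, 0.0144, 0.0213 and 0.0144, and adjusted p = 0.888 with an estimated correlation for each. No member passed limma as planned; with the library set term 5 oxidative phosphorylation genes passed, NDUFAB1 (0.51), NDUFB10 (0.45), SDHB (0.38) and COX5A (0.37) among them, and 11 adjusted over the list alone. In the mitochondrial ribosome list MRPS12 (0.41), MRPL36 (0.39) and MRPL11 (0.36) passed over all genes and 0 adjusted over the list alone, and of glycolysis PGK1 (0.38) passed and 0 adjusted over the list alone. Of the histones HIST1H4H (0.79), HIST1H2BD (0.59) and HIST1H1C (0.59) passed, and 5 adjusted over the list alone. No ribosomal protein or proteasome gene passed on either count (RPLP2 at 0.33 and PSMB2 at 0.35). With the library set term camera called these 6 and 5 more: nucleotide and polyamine synthesis (0.15), replication (0.13), chaperones (0.15) and immediate early genes (0.32) higher, and mitosis lower, with adjusted p between 0.0113 and 0.0490, and adjusted p = 0.806 with an estimated correlation for each. The mitosis median was 0.01, on the other side of 0 from the test and from the mean of -0.40, and 10 of 32 members were lower, CENPF, CENPE (-2.05), ASPM (-1.97) and TTK (-1.63) the most; adjusted over the list alone 10 were lower and 1 higher. Of the immediate early genes DUSP1 (0.78), JUND (0.63) and JUN (0.56) had higher responses. Higher and lower members numbered 4 and 1 in the nucleotide list, 1 and 0 in replication, 3 and 2 in chaperones and 4 and 1 in immediate early genes, and adjusted over the list alone 6 and 1, 1 and 0, 3 and 2, and 8 and 1. With quantile normalization none of the 6 calls held and the ribosomal proteins had a median of 0.02, and without Myc replicate 1 or control replicate 2 none of the 6 calls held except glycolysis (ribosomal proteins at 0.04 and -0.04). Glycolysis lost its call without control replicate 1 (0.09) or Myc replicate 2 (0.16), and after the GC content and length correction the planned calls of ribosomal proteins (-0.04), glycolysis (0.01), the mitochondrial ribosome (0.0023) and histones (0.26) ended. With the term quantile normalization ended each call but that of mitosis. The correction ended those of ribosomal proteins, glycolysis, the mitochondrial ribosome, replication (-0.03, on the other side of 0), chaperones (0.04) and immediate early genes (0.07). Chaperones (0.15) and immediate early genes (0.11) lost their calls with a pseudocount of 5, and mitosis and immediate early genes with no filter. Calls also ended for replication and chaperones with the stricter filter, and for all 4 lists without the trend in the prior spread. Among single genes the correction ended the calls of NDUFAB1 (0.27), NDUFB10 (0.11), SDHB (0.15), COX5A (0.06), MRPS12 (0.13), MRPL36 (0.08), MRPL11 (0.14), HIST1H2BD (0.34), HIST1H1C (0.26) and JUND (0.29).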

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

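The library set term, the removal of GC content and length trends, and the count of genes high in both Torin-1 differences were chosen only after the results were seen. So were the test of single interaction genes against the trend, the ratio of SDs and the share of variance between the library sets.

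The interaction test itself, which asks whether the Myc response differs between cells with and without Torin-1, drew attention to 1198 genes with the library set as a term. After each library's GC content and length trend was removed 841 genes passed, 80.9% of the 1039 called before on the same 9016 genes. Only 475 were called both times. The correction takes out 1 smooth trend per library, and no variation of the lone Torin-1 libraries enters the spread. A count that stayed high therefore cannot show that the trend falls short of these calls. For single genes the trend cannot be told apart from a Torin-1 effect: 52.8% of the 1039 kept over 0.5 of their log2 interaction. A smaller Torin-1 response in Myc-induced cells is a biological hypothesis that also stays open. Among genes of middle GC content and length the SD of the Torin-1 difference with Myc was 0.730 of that without Myc after the correction (0.677 before), and since each Torin-1 group had 1 library, an unusual Torin-1 library could give the same ratio.

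The same test, made by camera on the planned fit, drew attention to 6 gene lists with a higher Myc response in the presence of Torin-1. Their median interactions were 0.20 for cytosolic ribosomal proteins, 0.22 for glycolysis, 0.24 for the mitochondrial ribosome, 0.24 for oxidative phosphorylation, 0.17 for the proteasome and 0.59 for replication-dependent histones. None of the 6 calls held with quantile normalization. After the GC content and length correction those of ribosomal proteins (-0.04), glycolysis (0.01), the mitochondrial ribosome (0.0023) and histones (0.26) ended. None held with an estimated correlation either (camera adjusted p = 0.888 for each), but few residual degrees of freedom made that outcome close to fixed in advance. The estimates lay far above the preset 0.01 for ribosomal proteins (0.331), the mitochondrial ribosome (0.443), oxidative phosphorylation (0.377) and the proteasome (0.415), and not for glycolysis (-0.0094). Where the estimate was high, the p with the preset may be too small.

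Genes called higher with Torin-1 with the library set term, 52 in all, form another pattern. After the GC content and length correction 100% of the 51 called genes with a known transcript kept over 0.5 of their log2 change. That trend thus did not make up most of these changes. Selection favoured this outcome, since the additive fit counts a change in 1 Myc state as spread and the GC content trend lay mostly in the Torin-1 library. The called genes had a median GC content of 48.0%, against 48.9% in all tested genes, so the check says little about the trend as a cause. Over all 9016 corrected genes 169 lay above the 95th percentile both in Torin-1 minus control replicate 2 and in Myc plus Torin-1 minus Myc replicate 2. These differences share no library, and 32 and 3 genes lay in opposite tails. The counts argue against the Torin-1 library alone as the source of genes high in both Myc states, though not for each single gene. The differences are still not independent. Control and Myc replicate 2, which are subtracted, deviated together from their replicates (r = 0.933 across genes before the correction). A library set difference could thus put the same genes high in both. Lists fixed as checks of the RNA moved too: mitochondrially encoded genes had medians of 0.49 and 0.44 in these 2 differences (percentiles 99.99 and 99.98 of random lists) and replication-dependent histones 0.12 and 0.33 (91.0 and 99.96). The random lists were matched on mean expression but not on GC content or length. An effect of Torin-1 shared by both Myc states is a hypothesis. A handling difference shared by both Torin-1 libraries stays open beside it, as does a library set difference between them and replicate 2.

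Replicate 1 libraries stood apart from the other 4 across the transcriptome. GC content and transcript length accounted for 40.4% of the variance across genes of the difference between replicate 2 and replicate 1, between the bounds set for and against such a trend as the cause. A separate round of library making or a separate culture could each give this split and cannot be told apart here, because the labels give neither. No biological explanation was tested.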

How the results depend on the processing

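The library set term, every setting run together with it, the GC and length correction, and leaving out a Torin-1 library were chosen only after the results were seen. Of 132 named genes called after Myc induction with the term RPS2 lost its call under quantile normalization. With the correction 125 and with the stricter filter 122 of them were tested, and these were called again. Calls of other named genes were less stable. Of 19 named genes called for Torin-1 with the term 8 lost their call with no filter, 4 without the prior trend, 4 with a pseudocount of 5, 1 each with quantile normalization and median-ratio scaling. Leaving out libraries ended all 19 calls without control replicate 1 or Myc replicate 1, 8 without control replicate 2 and 10 without Myc replicate 2. Of 80 named genes called for the interaction with the term 34 lost it with no filter, 30 without the prior trend, 13 with a pseudocount of 0.1, 10 with quantile normalization and, besides EGR1, 2 with a pseudocount of 5, and with the correction 32 lost and 40 kept it. Low values near the floor and 2 replicates limit what these tests can show. By construction, leaving out 1 control or Myc library from a fit without the term unbalances Myc against the library set. Such shifts of the Myc and interaction results hold part of the difference between the sets. The cause of the shifts was not tested beyond what each setting does by its own construction.

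For Myc induction the planned count of 1 gene became 0 with no filter, 0 without the trend in the prior spread and 0 to 0 without each replicate. A replicate block gave 5735, as did the library set term, and 5825 passed with that term and the GC and length correction. The replicate numbers are shared by 2 pairs and the labels do not say that they mark a batch; deviations of same-numbered libraries from their group means correlated across genes (r = 0.933). For Torin-1 the count of 2 became 12 with a pseudocount of 5, 13 with the GC and length correction (PIM1 but not C8orf4 among them), 52 with the term, 223 with both, 0 for Torin-1 against control alone (825 at an unadjusted p under 0.05 in limma), 0 for Myc plus Torin-1 against Myc alone (118), and 0 to 2 without each library. With the term, 52 became 32 with a pseudocount of 5, 24 with no filter, 124 with the stricter filter, 223 with the correction (73.5% higher in place of 100%), 4557 and 484 in each Myc state alone, and 0 to 4549 without each library. A block with the Torin-1 libraries at their own level leaves no Torin-1 effect to estimate and was not made. For the interaction the planned 0 became 1198 with the replicate block or the term and 841 with the term and the correction, and 1198 became 660 with no filter. The share of higher interactions was 17.2% (206 genes) with the term, 6.21% (41) with no filter, 5.72% (55) without the prior trend, 13.3% and 19.1% with pseudocounts of 0.1 and 5, 32.6% with the stricter filter, 33.4% after quantile normalization, 29.6% after median-ratio scaling and 31.6% after the correction. With the term no fit without a replicate was possible for Myc or the interaction, since no residual degrees of freedom remain. The correlation of the Myc responses with and without Torin-1 went from 0.75 to 0.861 with the correction. EGR1's interaction with the term went from 0.45 to -0.033 with a pseudocount of 5.

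Every list call ended with an estimated correlation (0 lists in each of the 6 fits). The few residual degrees of freedom made this close to fixed in advance. Lists with an estimated correlation below the preset 0.01 lost their calls too. An example is nucleolar ribosome biogenesis after Myc induction with the term (correlation -0.020, camera adjusted p from 3.465e-11 to 0.513). Other called lists had estimates far above 0.01. In the planned Myc fit they were 0.716 for matrix, 0.622 for integrins, 0.443 for the mitochondrial ribosome and 0.331 for ribosomal proteins. With the term they were 0.113, 0.04, -0.020 and 0.901. The planned fit leaves the library set split in its residuals. For lists with high estimates the p with the preset may be too small. Without each library the Myc count of 16 lists was 10 to 14, and its cytosolic ribosomal protein median -0.42 to 0.025. The Torin-1 count of 6 was 16 with the correction, 17 with the term, 16 with both and 5 to 11 without each library, and with the term 17 was 11 to 20. The interaction count of 6 was 1, a different list, after quantile normalization and 11 with the replicate block or the term. With the term 11 was 1 after quantile normalization and 7 without the trend. Quantile normalization put the cytosolic ribosomal protein median at 0.038 for Torin-1 and 0.017 for the interaction with or without the term, and cytosolic chaperones at 0.012 for Torin-1 with the term.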

Other observations

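Several gene groups that camera did not call after Myc induction had members that rose and members that fell. This is not particular to these groups: of all 9537 tested genes 60.1% were called with the library set term, 2979 higher and 2756 lower. With the library set term, chosen after the data were seen, 12 of 30 nucleotide and polyamine synthesis genes rose and 10 fell. ODC1, the rate-limiting enzyme of polyamine synthesis and a textbook Myc target, rose from 284 ± 61.3 to 566 ± 149 FPKM and IMPDH1, of guanine nucleotide synthesis, by 0.97 on the log2 scale, while the deoxynucleotide synthesis gene RRM2 (-0.87) fell. In glycolysis 5 of 24 rose and 6 fell: HK2 rose from 15.8 ± 4.67 to 53.9 ± 9.69 FPKM and PDK1 by 0.83, while ALDOC fell by 1.19 and PFKFB4 by 0.92, and the list's median (-0.04) and mean (0.0023) lay on different sides of 0. Of 36 replication and E2F genes 10 rose, among them CDC25A (0.86), CCND2 (0.83) and CCNE1 (0.66), and 14 fell, TK1 by 1.08. In the FOXO and PI3K feedback list 7 of 20 rose, TXNIP by 1.70 and FOXO1 by 1.03, and 6 fell, PIK3IP1 by 1.14. Of 38 autophagy and lysosome genes 12 rose, such as TFEB (0.89), and 16 fell, with BNIP3L at -1.14 and CTSB at -1.05.

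Counts were 10 up and 16 down of 44 for oxidative phosphorylation (NDUFA2 at -0.75), 8 and 6 of 31 for the proteasome, 4 and 7 of 20 for the unfolded protein response (ERN1 at 0.99, PDIA4 at -0.86), 3 and 3 of 8 for the list of CDK inhibitors and Miz1-bound genes (CDKN1B at -0.89), 3 and 3 of 11 for hypoxia, 3 and 2 of 9 for inflammatory genes (ICAM1 at 0.76, NFKB1 at 0.66) and 0 and 0 of 5 for mitochondrially encoded genes. Camera adjusted p in the planned fit was at least 0.413 for each list not called but aminoacyl-tRNA synthetases. Of the marker lists of other cell types 1 of 16 epithelial and 2 of 21 blood and endothelial genes were in the table. LCP1 fell from 8.40 ± 1.84 to 4.65 ± 0.636 FPKM and CD68 from 8.0 ± 2.26 to 5.15 ± 0.0707 FPKM.

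The Myc plus Torin-1 and Myc replicate 2 libraries resembled each other more than any replicates did: their log2 values correlated across genes with r = 0.990, against 0.954 for the control replicates and 0.958 for the Myc replicates. Control replicate 2 and the Torin-1 library correlated with r = 0.960. With Torin-1 and the library set term the immediate early list was not called by camera (median 0.09, adjusted p = 0.0898): DUSP1, DUSP5 and FOSL2 rose and 0 fell. Adjusted over the list alone 6 rose and 5 fell, and EGR1 stood at -0.91 (limma adjusted p = 0.0647). The heat shock genes HSPA1B (-1.13, limma adjusted p = 0.0830) and HSPA1A (-1.08) and, chosen after its values were seen, SERTAD3 (-1.0, adjusted p = 0.0563) did not pass limma. DDIT3, which rose after Myc induction, stood at 12.8 ± 2.19 FPKM in control, 29.9 ± 4.31 FPKM in Myc, 44.0 FPKM in Torin-1 and 51 FPKM in Myc plus Torin-1. Its interaction was -0.96 with the term.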
